A study of Homo sapiens with 2 samples.

How the data were processed

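The series holds 2 single-cell RNA-seq libraries of SUM159 cells, a human breast carcinoma line, recovered from the lungs of immunodeficient NSG mice 3 days after injection into the tail vein. One library came from ITGB4-hi cells carrying a non-targeting guide (the control) and the other from ITGB4-hi cells with knockout of p63 and p73 (double knockout, dKO). Per the labels, 5 mice were injected, lungs were pooled within each group, tdTomato-positive cells were sorted, and 1 library per suspension was made with a droplet kit that reads the 3-prime ends of transcripts and tags each molecule with a unique molecular identifier (UMI). The loading aimed at 1250 cells per library. Whether the 5 mice were per group or in all is not stated in the labels.

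The deposited values are UMI counts per gene and cell barcode, written by Cell Ranger 4.0.0, per the file headers. The submitters' processing notes also name bcl2fastq and the builds GRCh38, hg38 and mm10, without a role for each. The feature list holds 36601 human genes and none from mouse, so how reads from mouse RNA were handled is not given in the sources used here, and part of the RNA of host cells can have been counted on human genes. The guide sequences and edited exons are likewise not given in the sources used here.

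Cells, lists and rules below were fixed before the data were examined, except where stated. Kept barcodes had at least 500 detected genes and at most 20% of UMIs in the 13 mitochondrially encoded genes. The deposited barcodes numbered 483 in the control and 474 in the dKO library. The gene minimum removed none, since the lowest deposited barcodes had 503 and 502 genes. The mitochondrial limit removed 15 and 17, leaving 468 and 457 cells with 20152623 and 17080318 UMIs. Scrublet, run in scanpy 1.11.5, marked 5 control and 18 dKO barcodes as doublets, which were kept in the main values.

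UMIs were summed over the kept cells of each library and divided by the library total (CPM). A gene was called measured with at least 100 UMIs over both libraries, which left 11123 genes. Ratios are dKO over control. Sums carry exact Poisson intervals, shares exact binomial (Clopper-Pearson) intervals, and ratios exact conditional binomial intervals, all at 95%. These cover counting error only. A count of 0 was set to a floor of 3 counts per library, which is 0.149 CPM in the control and 0.176 CPM in the dKO library, and the ratio is then a bound. List medians include such genes at their bound. With 1 library per group there is no replicate spread, so no test was run, no p-value is given and no gene is called changed. Knockout, any other difference between the cell populations, and the handling of the 2 suspensions cannot be separated by this design.

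Each of 22 gene lists was summarised by the median log2 ratio of its measured members, if it had at least 5, and by the number of members at least 1.5-fold higher or lower. The median was set against 10000 random lists of the same size drawn from the same of 20 expression bins. This describes the 2 libraries and is no test. Random ranges drawn anew from the ratios of an alternative were added after the data were seen. The lists cover hemidesmosome and laminin, basal epithelial and p63-associated, wound-edge keratinocyte, EGFR ligand, luminal and junctional epithelial, mesenchymal, S phase, G2/M phase, p53-family target, interferon-stimulated, NF-kB and cytokine, hypoxia and glycolysis, Notch and Wnt, YAP and TEAD, TGF-beta response, NRF2 and oxidative stress, immediate-early and heat shock, unfolded protein response, cholesterol synthesis, stem cell marker, oxidative phosphorylation and apoptosis regulator genes. Some genes stand in more than 1 list. Markers of other cell types in lung were given as UMI sums.

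Named genes followed a fixed rule: TP63, TP73 and ITGB4; the 12 highest and 12 lowest log2 ratios among measured genes found in at least 10% of the cells of the higher library with no cell holding over 20% of the gene's UMIs there, leaving out mitochondrially encoded, ribosomal protein, Y-linked genes and XIST; and from each list up to 4 measured members with the largest absolute ratio if the median lay outside the central 95% of its random lists, otherwise up to 2. Other genes named, such as list members that ran against their list, were chosen after their values were seen, except MKI67 and TOP2A. A few members the rule takes from the lists are not reported here. Coordinates came from GENCODE 29 on GRCh38, matched by Ensembl identifier for 11076 of the 11123 measured genes. The annotation release behind the deposited counts is not given in the sources used here, so gene ends may differ slightly.

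Cell cycle phases were called with scanpy from the S and G2/M lists after thinning every cell to 1655 UMIs, the 10th percentile of depth, which left out 74 control and 19 dKO cells. Cells were clustered with the Leiden method (scaling to 10000 per cell, 2000 variable genes, 30 components, 15 neighbours, resolution 0.5). Alternatives were no cell filter, a stricter one (at least 1500 genes and at most 10% mitochondrial UMIs), leaving out doublets, scaling by TMM (edgeR 4.0.16, scaling factors only), by the median ratio or without mitochondrial and ribosomal protein genes, weighting cells equally, thinning, minimums of 30 and 300 UMIs, and cells called G1 only. For the G1 alternative the phases were called on unthinned cells. A filter at 1500 genes alone and thinning to 10000 UMIs were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.

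The steps were tested on simulated counts with known ratios, drawn for the dKO over control comparison with Poisson error only. Over 11147 simulated measured genes, 95.7% of intervals held the true ratio. Of 98 measured genes simulated at 2-fold, 99.0% came out beyond 1.5-fold in the right direction, as did 100.0% of 94 at 4-fold, against 0.293% of unaltered genes beyond 1.5-fold. Of 200 random lists without any difference, 5.0% fell outside the central 95%. Variation between cells, animals or cultures was not part of the simulation.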

Results

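Cells of the ITGB4-hi subline of SUM159, a human breast carcinoma line with mesenchymal features, were profiled one by one after 3 days in mouse lung. The single comparison set cells with a non-targeting guide (control) against cells with knockout of p63 and p73 (dKO), related transcription factors of which p63 is known for maintaining basal epithelial identity. It addresses which parts of the epithelial program of these cells depend on the 2 factors at an early stage of lung colonization. Each group gave 1 library, so the values below have no replicate check and differences describe the 2 libraries, which may also differ for reasons other than the knockout. The control library held 468 kept cells with a median of 40320 UMIs and 5766 genes per cell, and the dKO library 457 cells with 33400 UMIs and 5346 genes.

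Depth was uneven within the control library. Barcodes under 1500 genes made up 27.8% of its cells (130 of 468, 95% interval 23.8 to 32.1) against 8.10% in the dKO library (37 of 457, 5.76 to 10.99). They carried 1.11% and 0.392% of the UMIs. Values from summed UMIs therefore rest almost entirely on the deeper cells, and without these barcodes the median of each list differed little (basal -2.89, mesenchymal 2.26, S phase -0.46). The median share of mitochondrially encoded UMIs was 8.23% in the control and 9.70% in the dKO library.

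**Figure D1:**
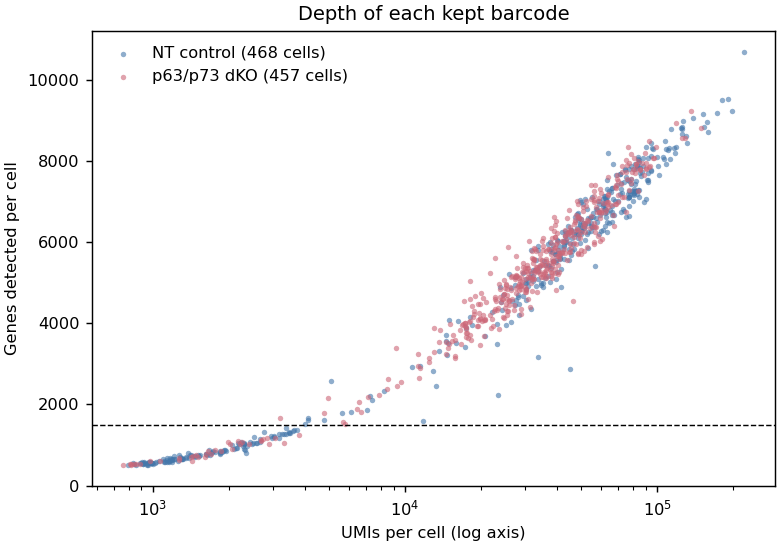
Genes detected against UMIs (log axis) for every kept barcode of the control (468) and dKO (457) libraries; each point is 1 barcode and the dashed line marks 1500 genes. The group of points under the line holds 130 control and 37 dKO barcodes.

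Transcripts of both targeted genes and of ITGB4 were lower in the dKO library. TP63 (chromosome 3, 189631416 to 189897279) had 941 UMIs in the control (95% interval 882 to 1003) and 233 in the dKO library (204 to 265), 3.42-fold lower in CPM (2.96 to 3.97). TP73 (chromosome 1, 3652520 to 3736201) had 319 (285 to 356) and 23 (14.6 to 34.5), 11.8-fold lower (7.70 to 18.8). ITGB4 (chromosome 17, 75721328 to 75757818), the integrin beta-4 gene in the subline's name, had 550 (505 to 598) and 19 (11.4 to 29.7), 24.5-fold lower (15.6 to 41.1). Its log2 ratio of -4.62 was -3.61 with cells thinned to equal depth. That value rests on few UMIs, since only 20 of 394 control and 2 of 438 dKO cells then had an ITGB4 UMI. The tags come from transcript 3-prime ends, which can lie outside the edited part, so the remaining TP63 UMIs do not measure remaining protein.

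Genes of the basal epithelial layer were lower together. Of 13 measured basal epithelial and p63-associated genes, 12 were at least 1.5-fold lower in the dKO library and 0 higher, against a median of 2 lower in random lists. The list median was -2.87 on the log2 scale, below the central 95% of random lists (-0.33 to 0.37). The basal keratins KRT17, KRT14 and KRT5 were 288-fold (165 to 558), 226-fold (110 to 564) and 162-fold lower (44.6 to 1345), with 12, 7 and 2 UMIs left in the dKO library. S100A2, a calcium-binding protein gene and known p63 target, was at 8119 CPM in the control and 279 CPM in the dKO library, 29.1-fold lower (28.3 to 29.98). RIPK4 was the member not beyond 1.5-fold, at a log2 ratio of 0.19 (-0.01 to 0.40).

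Hemidesmosome genes, whose products anchor basal cells to the basement membrane, had a median of -1.54 (random range -0.44 to 0.31). Of 11 measured members 8 were at least 1.5-fold lower and 0 higher, against a random median of 2 lower. Besides ITGB4 these included its partner integrin ITGA6, 10.2-fold lower (8.79 to 11.9), and the adhesion adaptor FERMT1, 3.89-fold lower (3.24 to 4.69). Wound-edge keratinocyte genes had a median of -1.02 (random range -0.37 to 0.33), with 8 of 12 lower and 2 higher. The cytokine IL1A was 188-fold lower (80.5 to 581), IL1B 24.5-fold (15.6 to 41.1) and the keratin KRT16 27.1-fold lower (10.3 to 101), and KRT6A, with 109 UMIs against 0, at least 30.8-fold lower. The 2 members that were higher were the fibronectin gene FN1 and the integrin gene ITGA5. The wound-edge median was -0.65 with the stricter cell filter, over 1.5 times closer to 0.

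Among epithelial junction and simple-epithelial genes, 6 of 27 were measured, 4 lower and 1 higher, with a median of -1.16 (random range -0.53 to 0.46). The keratin KRT7 was 4.57-fold lower (4.43 to 4.73), the desmosome genes DSP and JUP 3.57-fold (2.96 to 4.33) and 2.25-fold lower (1.92 to 2.66), and CD24 2.23-fold lower (1.47 to 3.46). KRT8 was the member that was higher. The median was -0.60 when members with 30 UMIs were admitted. CDH1, the E-cadherin gene, had 0 UMIs in both libraries. Only 3 genes of the EGFR ligand list were measured, too few for a median. EREG had 320 and 61 UMIs and HBEGF 502 and 260. When members with 30 UMIs were admitted, 6 had a median of -1.16, below a random range drawn anew there (-0.48 to 1.01).

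Mesenchymal genes were higher in the dKO library. Of 27 measured members 24 were at least 1.5-fold higher and 0 lower, against a random median of 4 higher, and the median was 2.27 (random range -0.27 to 0.16). COL1A1, a chain of type I collagen, had 814 UMIs in the control and 27021 in the dKO library, 39.2-fold higher (36.5 to 42.1). The type VI collagen genes COL6A3 and COL6A2 were 77.9-fold (63.1 to 97.4) and 47.0-fold higher (40.7 to 54.5). POSTN, the gene of the matrix protein periostin, had 1 UMI in the control and 238 in the dKO library, a ratio of 281 (49.9 to 11137). The markers of fibroblasts, a cell type of the host lung, summed to 1719 UMIs in the control and 58460 in the dKO library. Most of the dKO sum came from COL1A1, COL3A1 (650 and 16627 UMIs) and MGP (182 and 13065). PDGFRB had 21 and 1421, while COL1A2, the second chain of type I collagen, had 1 and 88 and DCN 4 and 90. PDGFRA had 39 and 79, LUM 2 and 69 and TCF21 6 and 0. Single dKO cells held 46.7% of the DCN and 62.3% of the LUM UMIs of that library. The list of mesenchymal genes shares COL1A1, COL1A2 and COL3A1 with those markers.

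**Figure D2:**
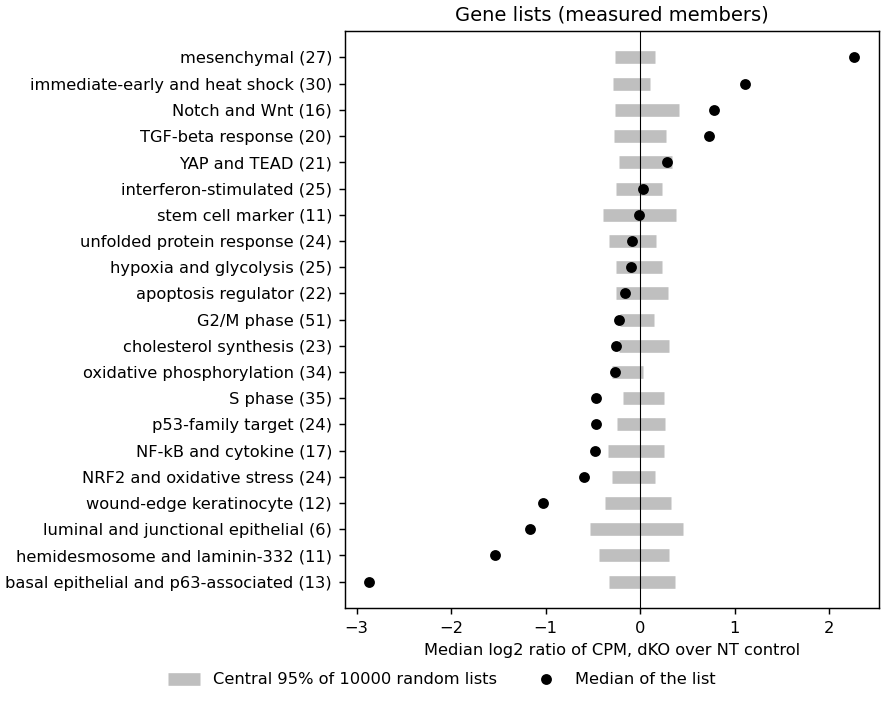
Median log2 ratio of CPM (dKO over control) of each gene list with at least 5 measured members (black points; number of measured members in brackets), with the central 95% of 10000 expression-matched random lists in grey. The mesenchymal median of 2.27 and the basal epithelial median of -2.87 lie farthest from 0.

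Over all 11123 measured genes the median log2 ratio was 0.03, and 1062 genes were at least 2-fold higher and 581 at least 2-fold lower. These counts describe size and carry no test. TMM scaling would shift every log2 ratio by -0.13, and the ratios here are relative to the total UMI count. Among the 12 highest, NES (nestin, an intermediate filament; chromosome 1, 156668763 to 156677397) had 1 and 327 UMIs, a ratio of 386 (68.8 to 15285), and PCOLCE, a procollagen-processing enhancer (chromosome 7, 100602177 to 100608175), 8 and 2528 UMIs, 373-fold higher (189 to 865). BEX1 and LINC01142, with 0 control UMIs, were at least 186-fold and 160-fold higher. The others were POSTN, SCG2, PRKG1, the laminin chain LAMA4, GALNT15, APCDD1, PLPP4 and the collagen COL5A3, with ratios from 113 (COL5A3) to 281 (POSTN).

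Among the 12 lowest, MIR205HG, the host gene of the epithelial microRNA miR-205 (chromosome 1, 209428820 to 209432838), had 3624 UMIs in the control and 0 in the dKO library, at least 1024-fold lower. PLCH2 and TMEM40 also had 0 dKO UMIs and were at least 110-fold and 81.4-fold lower. PPP1R14C, with 699 and 1 UMIs, had a log2 ratio of -9.21 (-14.52 to -6.73). KRT75, a keratin of chromosome 12 (52424070 to 52434525), was 302-fold lower, beside KRT17, KRT14, KRT5 and IL1A given above. AC245041.2, the aldehyde dehydrogenase gene ALDH1A1 and AMTN, with 3, 1 and 2 dKO UMIs, had log2 ratios of -7.18 (-9.46 to -5.62), -6.81 (-12.12 to -4.30) and -6.67 (-9.73 to -4.81). Thinning to 1655 UMIs left 1611 measured genes, and 4 of the 24 genes then remained in the ranking.

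**Figure D3:**
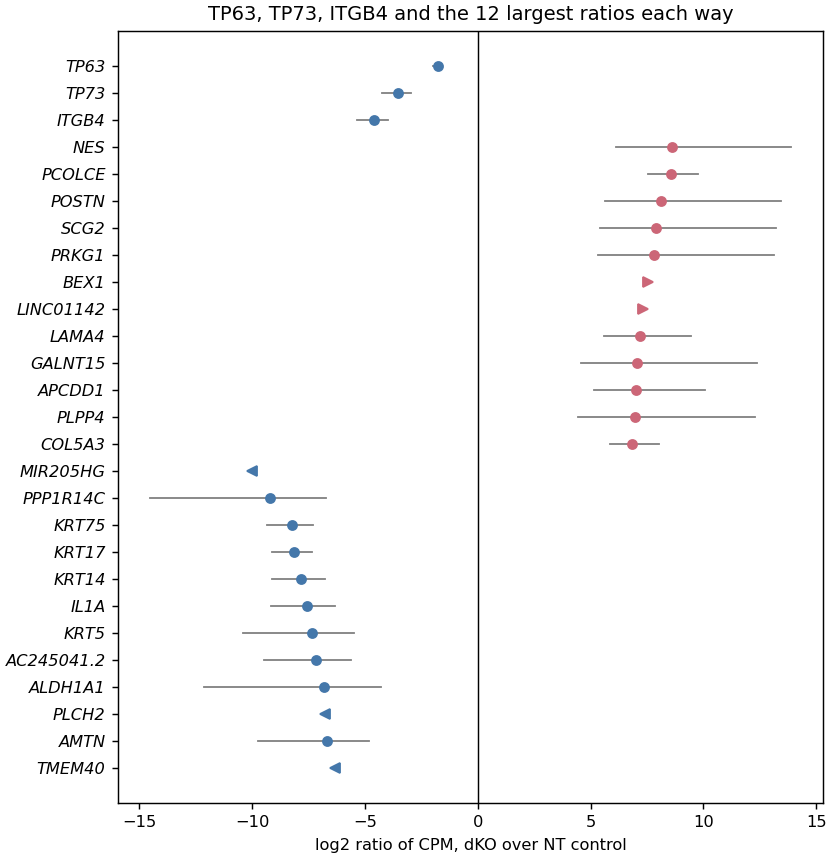
Log2 ratio of CPM (dKO over control) for TP63, TP73, ITGB4 and the 12 highest and 12 lowest genes; lines are 95% intervals for counting error, and triangles mark bounds for genes with 0 UMIs in 1 library. Ratios of the 12 highest lie between 6.82 and 8.59 and those of the 12 lowest between -10.00 and -6.35.

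DNA replication genes were lower in the dKO library, with a median of -0.46 (random range -0.18 to 0.25) and 11 of 35 members at least 1.5-fold lower, against a random median of 5, and 0 higher. UHRF1 had a log2 ratio of -1.04 (-1.35 to -0.73), CDC6 -0.93, FEN1 -0.83 and DTL -0.81. Mitosis genes had a median of -0.22, just outside the random range (-0.21 to 0.15), with 9 of 51 lower, against a random median of 7, and 0 higher. The median was -0.85 with cells thinned, over only 9 measured members, against a random range of -0.63 to 0.28 drawn anew. It was -0.21 without doublets, inside a random range drawn anew for those cells (-0.22 to 0.13). Resampling of cells with at least 10000 UMIs, measured on the UMIs beyond 10000, was added after the data were seen. The mitosis median was then -0.14 (-0.57 to 0.28), an interval that includes 0, and the replication median -0.45 (-0.69 to -0.16). The securin gene PTTG1 was at -1.30 (-1.36 to -1.24), RANGAP1 at -1.16, ANLN at -0.85 and CCNB1 at -0.81, while the proliferation markers MKI67 (-0.08, -0.19 to 0.02) and TOP2A (-0.13, -0.23 to -0.02), chosen in an alternative set beforehand, were close in the 2 libraries. Of cells thinned to 1655 UMIs, 53.05% were called S or G2/M in the control (209 of 394, 48.0 to 58.1) and 26.9% in the dKO library (118 of 438, 22.8 to 31.4). Unthinned shares were 51.1% and 25.4%, and at 10000 UMIs 42.8% and 22.7%. Without the low-depth barcodes they were 49.4% and 28.1% in cells with at least 1500 genes and 49.0% and 32.4% with the stricter cell filter. The scores can also read free RNA, so no difference in cycling is read from the phase calls alone. The share of cells with an MKI67 UMI was 9.64% in the control (6.92 to 13.0) and 6.39% in the dKO library (4.29 to 9.11) at 1655 UMIs, and 35.8% (30.6 to 41.2) and 23.0% (19.0 to 27.4) at 10000 UMIs.

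**Figure D4:**
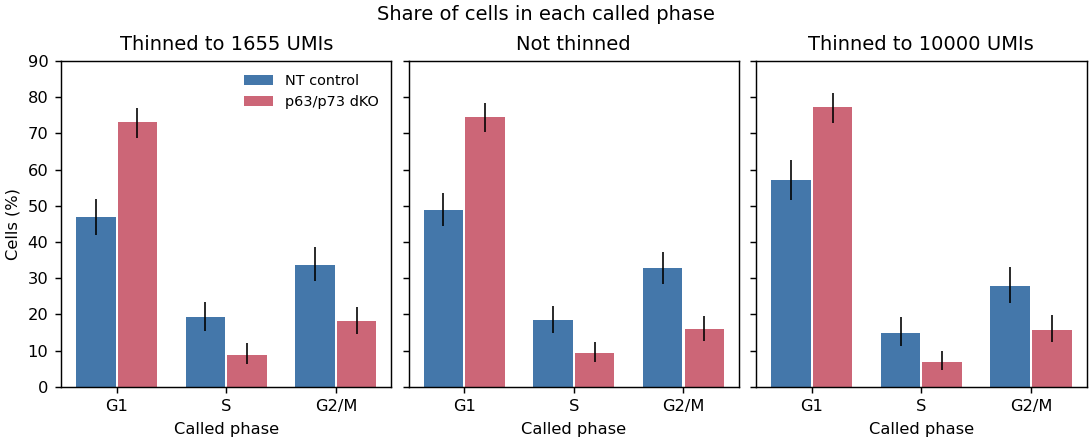
Percent of cells called G1, S or G2/M in the control and dKO libraries at 3 settings of depth; bars are shares and lines exact binomial 95% intervals for counting error. At 1655 UMIs 47.0% of control and 73.1% of dKO cells were called G1.

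Among signalling lists, immediate-early and heat shock genes had a median of 1.11 (random range -0.28 to 0.10), with 20 of 30 higher and 6 lower. The early transcription factor genes EGR2 (3.89, 3.11 to 4.79), NR4A1 (3.18, 2.87 to 3.50) and MYC (2.46, 2.40 to 2.53) and the mRNA decay factor ZFP36 (2.69, 2.62 to 2.76) had the largest ratios. This list responds to tissue dissociation, and each library came from its own suspension. TGF-beta response genes had a median of 0.73 (-0.28 to 0.27), 13 of 20 higher and 1 lower, with LMCD1 at 2.33, TGFBI at 1.95, LTBP3 at 1.92 and ID2 at 1.62. Notch and Wnt genes had a median of 0.78 (-0.26 to 0.41), 9 of 16 higher and 3 lower. The receptor NOTCH3 (4.32, 3.84 to 4.84) and the Notch effector HEY1 (2.57) were higher, and the ligand DLL1 (-2.68) and the Wnt inhibitor RNF43 (-1.91) lower. With each cell weighted equally the Notch and Wnt median was 0.56, just inside its random range (upper limit 0.57).

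The p53-family targets had a median of -0.46 (-0.24 to 0.27), 11 of 24 lower and 1 higher. CDKN1A, the cell cycle inhibitor p21, was at -2.20 (-2.45 to -1.95), FDXR at -1.95, AEN at -1.80 and PHLDA3 at -1.59. NF-kB and cytokine genes had a median of -0.47 (-0.34 to 0.26), 8 of 17 lower and 4 higher; CSF2 (-4.57), the adhesion receptor ICAM1 (-2.12) and IL32 (-1.57) were lower and IL6 (2.67) higher. With cells thinned the NF-kB median was -1.34, over only 5 measured members. Antioxidant genes under NRF2 had a median of -0.59 (-0.30 to 0.16), 12 of 24 lower and 3 higher, with AKR1C2 at -3.52, GCLM, a subunit of the glutathione-making ligase, at -1.76, SRXN1 at -1.31 and AKR1B10 at 1.74. Cholesterol synthesis genes had a median of -0.25 (-0.22 to 0.31). Of 23 members 4 were lower, close to a random median of 3, and 1 higher, against a random median of 4. The enzymes SQLE (-2.14) and DHCR7 (-1.28) were lower and STARD4 (1.12) higher. The cholesterol median was -0.09 with each cell weighted equally and -0.23 without doublets, inside the random ranges drawn anew there (lower limit -0.24 in both).

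The other 7 lists had medians inside their random ranges. Interferon-stimulated genes had a median of 0.03 (6 of 25 higher and 4 lower; IFI44L 2.19, IRF9 2.02), hypoxia and glycolysis -0.10 (5 of 25 higher and 7 lower; the glucose transporter gene SLC2A3 3.18, PFKFB4 -2.12) and YAP and TEAD targets 0.28 (6 of 21 higher and 5 lower; CCN2 3.41, ARHGEF17 3.14). Unfolded protein response genes had a median of -0.09 (3 of 24 higher and 8 lower; DDIT4 2.23, SLC3A2 -1.12). Breast cancer stem cell markers had a median of -0.01, with 3 of 11 higher, among them NES, and 3 lower, among them ALDH1A1. Oxidative phosphorylation subunits had a median of -0.27 (0 of 34 higher and 4 lower; CYCS -1.36, CYC1 -0.73) and apoptosis regulators -0.16 (4 of 22 higher and 6 lower; BMF 2.58, TNFRSF10A -1.73). The hypoxia median was -0.48 with cells thinned, over 7 measured members. The YAP median was 0.082 in cells called G1. It was 0.50 with each cell weighted equally and 0.36 with the stricter cell filter, both above random ranges drawn anew there (upper limits 0.47 and 0.31). By the same measure the oxidative phosphorylation median was below its range with 300 UMIs required (-0.27, lower limit -0.25), and the other 5 lists stayed inside under each alternative computed for them.

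The kept cells formed 5 clusters, the most mixed of them 94.6% from 1 library, so that a cluster may be a library and not a cell type. With cells thinned to 1655 UMIs there were 4 clusters, and 54.8% of cells were in clusters at least 90% from 1 library. Apart from the fibroblast markers given above and CAV1, UMIs of markers of other lung cell types were few. The feature list holds human genes only, so RNA of mouse cells can have been missed. These sums therefore do not measure how many host cells were present. UMI sums in the control and dKO libraries were 57 and 242 for macrophage and monocyte markers, of which 2 and 101 were PTPRC, 8 and 10 for neutrophil, 9 and 24 for lymphocyte, 117 and 58 for endothelial, 1 and 11 for mesothelial, 6 and 108 for erythroid and 12 and 64 for platelet markers. ERG held 111 of the control endothelial UMIs, over 86 cells, and GP1BB 58 of the dKO platelet UMIs, over 56 cells. The alveolar and airway sums, 14011 and 12140, were almost all CAV1 (13977 and 12089), a gene these cancer cells also express. Among the cells' own types, basal epithelial markers summed to 14347 and 1226 UMIs, luminal to 10295 and 12134 (almost all KRT8, 3772 and 6778, and KRT18, 6501 and 5327), mesenchymal to 253445 and 331253 (of which VIM, 243201 and 274678), S-phase to 8741 and 5470 and G2/M to 18837 and 13245.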

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

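All list medians, the ratios of TP63, TP73 and ITGB4, the 24 ranked genes, phase shares and cluster mixing were recomputed under each alternative that applied to them. No median outside its random range changed sign. Of 241 recomputed list medians, 182 stayed inside the counting interval of the reported value and 59 moved outside it; the interferon and stem cell medians, close to 0, took either sign. TP63 ranged from -2.25 to -1.71, the basal median from -3.60 to -2.84 and the mesenchymal median from 2.08 to 2.71. No cell filter, leaving out doublets, totals without mitochondrial and ribosomal protein genes and, added after seeing the data, cells with at least 1500 genes moved none of the values computed under them. With 1 library per group, counting intervals are narrow and cover no variation between animals or cultures. No paired analysis was possible because each group has 1 library. Where the construction of an alternative does not show it, the cause was not tested.

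With the stricter cell filter, which kept 194 and 204 cells, the medians were hemidesmosome -1.76, wound-edge -0.65, S phase -0.33 and oxidative phosphorylation -0.25; 15 of the 24 ranked genes were shared, and 49.0% of control and 32.4% of dKO cells were called S or G2/M. TMM scaling, which lowers all ratios, gave hemidesmosome -1.67, wound-edge -1.15, S phase -0.59, G2/M -0.35, interferon -0.093, NF-kB -0.60, TGF-beta 0.60, NRF2 -0.72, immediate-early 0.98, unfolded protein response -0.21, cholesterol -0.38, stem cell -0.14, oxidative phosphorylation -0.39 and apoptosis -0.28. Scaling to a median ratio of 0 gave immediate-early 1.08 and oxidative phosphorylation -0.30. With cells weighted equally, the values were S phase -0.60, G2/M -0.47, p53-family -0.65, Notch and Wnt 0.56, YAP 0.50, TGF-beta 0.86, NRF2 -0.71, immediate-early 1.26, unfolded protein response -0.20, cholesterol -0.088, stem cell -0.13 and oxidative phosphorylation -0.31.

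Thinning to 1655 UMIs left 1611 measured genes, so lists rest on fewer and more abundant members. It gave TP63 -2.25, ITGB4 -3.61, mesenchymal 2.71, G2/M -0.85, interferon 0.26, NF-kB -1.34, hypoxia -0.48, TGF-beta 0.89, NRF2 -0.69, immediate-early 1.14 and oxidative phosphorylation -0.30; 4 of the 24 ranked genes were shared, and 54.8% of cells were in clusters at least 90% from 1 library. Admitting members with 30 UMIs gave luminal -0.60, interferon 0.22 and stem cell -0.12. The EGFR ligand list, which had no reported median, then had a median of -1.16. Requiring 300 UMIs gave wound-edge -0.84, p53-family -0.66, NF-kB -0.61, immediate-early 0.92, stem cell 0.10 and 15 of 24 shared genes. Cells called G1, 229 control and 341 dKO, came from calls without thinning, which can depend on depth. Their values were basal -3.60, wound-edge -1.19, luminal -1.55, S phase -0.34, NF-kB -0.59, hypoxia -0.25, YAP 0.082, NRF2 -0.78, immediate-early 0.89 and oxidative phosphorylation -0.29. In place of phase calls, an MKI67 UMI was found in 9.64% of control and 6.39% of dKO cells and a TOP2A UMI in 8.88% and 7.76%, which are lower by construction. Thinning to 10000 UMIs, added after seeing the data, gave 42.8% and 22.7% in S or G2/M, an MKI67 UMI in 35.8% (30.6 to 41.2) and 23.0% (19.0 to 27.4), and a TOP2A UMI in 103 of 327 control (26.5% to 36.8%) and 81 of 405 dKO cells (16.2% to 24.2%), so the intervals for these shares overlapped at 1655 UMIs and were apart at 10000.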

Other observations

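All tests in this part, and the genes it singles out, were chosen after the results were seen. Some single genes outside the lists were higher in the dKO library. APOE, the gene of apolipoprotein E, had 1276 UMIs in the control and 10162 in the dKO library, 9.40-fold higher in CPM. SCG5, a secretory granule gene, had 57 and 2594 (53.7-fold), the growth factor gene PTN 1563 and 8163, FSTL1 544 and 2753 and NREP 1154 and 8180. SOCS3, a feedback inhibitor of cytokine signalling, had 111 and 2740 (29.1-fold). S100A4, which is a member of the mesenchymal list, had 8342 and 73784 UMIs.

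Other single genes outside the lists were lower in the dKO library. The collagen receptor gene ITGA2 had 4510 and 420 UMIs, 9.10-fold lower, and the syndecan gene SDC1 1818 and 63, 24.5-fold lower. IGFBP7 had 7342 and 645 (9.65-fold), the lysosomal protease gene CTSC 16581 and 2442 (5.75-fold) and TNFRSF12A 9532 and 1689. Within type I collagen the chains were unequal, with 88 COL1A2 UMIs beside 27021 of COL1A1 in the dKO library. A few cells in each library held most UMIs of the antiviral gene OASL: the 6 control cells with at least 10 had 97.3% of its 401 UMIs, and 7 dKO cells had at least 10, of 320 in all. A single dKO cell held 102 of the 103 HBB UMIs.

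The control library had more low-depth barcodes than the dKO library (27.8% and 8.10% of cells). Intact cells with little RNA are argued against by the nuclear transcript MALAT1, whose share in these control barcodes was 0.113 of that in deeper cells. Mouse cells as the sole source are argued against by the 12 genes highest in the control, whose share was 0.683 of that in deeper cells (0.568 to 0.813), although MTRNR2L12, whose sequence resembles mitochondrial ribosomal RNA, was 3.99 times higher and droplets with a host cell and free human RNA stay open. Mitochondrially encoded UMIs had 0.164 of their share in deeper control cells, and 0.447 in the dKO library. Free or fragmentary cytosolic RNA would give a low share. So could droplets with a host cell and free human RNA, since only human genes were counted. The value does not tell these sources apart. MTRNR2L12 was also 4.50 times higher in low-depth than in deeper dKO barcodes. Why the libraries differed in low-depth barcodes was not tested, and an effect of the knockout stays open.

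Collagen and other mesenchymal genes were higher in the dKO library. A minority of host fibroblasts among the sorted cells is argued against by the distribution over cells: in 94.5% of dKO cells with at least 1500 genes (397 of 420, 91.9 to 96.5), the summed share of the 24 higher members lay above the 95th percentile of control cells. Members were picked here for being higher, and S100A4 held 37.8% of their dKO UMIs. Without it the share of cells was 86.4% (82.8 to 89.6), and with all 27 measured members 60.5% (55.6 to 65.2). With the 9 fibroblast markers, fixed beforehand, it was 95.95% (93.6 to 97.6), against a control 95th percentile of only 0.041% of UMIs. COL1A1 and COL3A1 held most dKO UMIs of those markers and are also among the 24 members, so the sets overlap. Single dKO cells held 46.7% of DCN and 62.3% of LUM UMIs, so a few host fibroblasts as a source of those genes stay open. Free RNA of host cells as the main source, which would add a similar number of UMIs to each droplet, is argued against by a median count of these members 5.07 times higher in the 114 deepest dKO cells than in the 115 shallowest, 4.51 times without S100A4 (3.22 to 6.44 over resampled cells) and at medians of 162 against 30 UMIs for the fibroblast markers (3.74 to 8.42 times). The share of COL1A1 was 1.72 times higher in low-depth than in deeper dKO barcodes (1.48 to 1.99), while those of MGP and COL3A1 were 0.761 and 0.720 times as high, so a contribution of free RNA to COL1A1 stays open. That the knockout raises these genes is a hypothesis that remains. A difference between the injected populations that predates or accompanies the knockout, such as outgrowth of a subpopulation, may equally account for it, since the design has 1 population per group. Independently made knockout populations, or return of p63 and p73 to the knockout cells, would tell these apart.

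Immediate-early genes were higher in the dKO library, at 18 of 20 members, while of 10 heat shock and chaperone genes 2 were higher and 5 lower. Fewer cycling cells as the whole cause are argued against by a comparison of 405 dKO cells with the 145 control cells called G1 without an MKI67 or TOP2A UMI, called on 10000 UMIs per cell and measured on their other UMIs. These control cells had fewer cycling transcripts than the dKO cells (S phase median 0.66, G2/M 2.65), yet the list median was 0.80 (0.61 to 1.05 over resampled cells), against 1.10 with all 327 control cells at that depth. A difference in dissociation and sorting between the suspensions cannot be told apart from an effect of the knockout: the inducible heat shock genes HSPA1A, HSPA1B and DNAJB1 had a median log2 ratio of 1.57, but the heat shock part as a whole was at -0.62, and each group had its own suspension.

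The remaining S100A2 and ITGB4 UMIs of the dKO library raised the hypothesis that a minority of its cells may have kept a control-like program. In S100A2, 0 of 420 dKO cells with at least 1500 genes reached the 5th percentile of control cells (33.1 per 10000 UMIs), which allows a share of such cells of up to 0.874%; the highest had 31.9. Yet 11 of the 420 fell in clusters made up mainly of control cells, with a median of 2.20 S100A2 UMIs per 10000, against 1.75 in the 420 and 75.4 in control cells, and the cell with 31.9 was among them. Their median share of the 24 mesenchymal members, 0.339%, was below that of the 420 (1.15%) and above that of control cells (0.142%). Of the 11, 5 lay above the 95th percentile of control cells in that share. The 11 held 0 ITGB4 and 0 KRT17 UMIs. In the other direction, 5 and 1 of the 468 kept control cells fell in the clusters made up mainly of dKO cells. Further, 1 cell held 6 of the 7 KRT14 UMIs of the dKO library, another 9 of the 12 KRT17 UMIs and another all 4 KRT16 UMIs. The KRT14 cell was among the 11, while the KRT17 and KRT16 cells lay in the main dKO cluster with 1.77 and 4.05 S100A2 UMIs per 10000, as in other dKO cells. A minority that kept part of the control program therefore stays open. The share of S100A2 was 2.97 times as high in low-depth as in deeper dKO barcodes (2.23 to 3.87). A contribution of free RNA to the remaining S100A2 UMIs thus stays open as well. A second hypothesis was that basal genes follow the TP63 level among control cells. At 10000 UMIs, 125 control cells with a TP63 UMI and 202 without had a basal median ratio of 0.06, at percentile 83.6 of random lists, with only 5 measured members, which leaves it open. The hemidesmosome median was 0.14 over 9 members, at percentile 95.3 and inside the central 95% of random lists (-0.10 to 0.16). The mesenchymal median in the same comparison was 0.24 over 9 measured members, at percentile 99.97, higher in cells with a TP63 UMI. That is not the direction of the comparison between libraries, which rested on 27 measured members and so on an unlike set of genes.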
